A study of Homo sapiens with 6 samples.

How the data were processed

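RNA sequencing of 6 libraries, 3 controls and 3 FOXO3 knockouts, was analysed from the gene table that the authors deposited. Per the labels' protocols, cells labelled U-937 were grown in RPMI medium with serum, FOXO3 was knocked out with small guide RNAs, and libraries were made from total RNA with a SMARTER kit for mRNA. The guide sequences, the edited site and the strand setting are not given in the sources used here. The deposited values are FPKM, fragments scaled to transcript length and library size, per the file headers, with 1 column per library. Per the submitters' processing notes, the build was hg38 and the tools were Bowtie 0.12.9, Cufflinks 2.1.1 and HTSeq, with no role given for any of them. Row identifiers in the deposited table mix 35986 Ensembl genes with 20432 loci of the form used for merged transcript assemblies, so a value can include transcripts that the reference annotation lacks, and a change of isoform can move it.

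The table has 56418 rows. A value of exactly 0.0001 stood in 60.7% to 62.4% of the rows of each library and is treated as a floor. Several genes were named together in 1527 rows, which were tested as loci and are not given as single genes. Rows of the same name were summed after 4865 repeats with identical values had been dropped, which left 47102 names. In all, 99.0% of the transcript identifiers were in GENCODE release 29 (GRCh38), which gave transcript lengths, GC content and coordinates. Genes that share sequence with close copies, such as histones and EEF1A1P6, and overlapping genes are uncertain because the treatment of shared reads is not given in the sources used here.

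FPKM does not hold counts. In rows with 1 annotated transcript, FPKM times length came in steps, and 68.8% to 74.5% of the low values lay within 0.1 of a whole step, against 20% by chance. The step was read as 1 aligned base, which gave the depth of each library. The most frequent value in these rows was 282 steps in every library, about the size of a read pair. It was sought only in a preset window around that size, so its rough size is weak support for this reading. On this reading the steps are bases and not whole reads, so no count model was run.

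The main test was limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with group as the only term, a mean-variance trend and two-sided Benjamini-Hochberg adjustment at 0.05, over genes with a mean of at least 1 FPKM. A fold change on this scale understates the change of genes with low values. Group values are means ± SD of FPKM over 3 libraries. Of 29 gene lists, the 24 with at least 5 tested members were tested with camera (preset correlation 0.01), with an estimated correlation and with fry, adjusted over the lists. In 3 against 3 libraries, same-numbered libraries were not treated as pairs. The groups, tests, gene lists, most alternatives and the rule for named genes were fixed before the data were examined. That rule took FOXO3, the 12 largest rises and falls past the threshold without overlap of the groups, up to 4 members of each list with the smallest p, and the best-known FOXO targets and paralogs. Names of several genes, clone names, RNA family names, antisense names and unnamed loci were left out of it.

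On simulated data for this comparison (11162 genes), limma recovered 36% of 50 genes changed 1.5-fold, 76% at 2-fold, 94% at 3-fold and 98% at 4-fold, with 12 false calls among 164. Of 200 unchanged lists, 9 fell below an unadjusted p of 0.05 in camera. The simulated noise was independent between genes, so this count does not cover lists whose members vary together. The real lists included such cases, with an estimated correlation of 0.591 among cytosolic ribosomal protein genes. Alternatives covered the pseudocount, the filter, the scaling, the variance trend, a replicate block, the choice of row per gene, the set test, each library left out in turn and, chosen after seeing the data, the removal of a trend with transcript length and GC content (natural splines with 4 degrees of freedom each), that removal without the second control library, and rows naming several genes counted for the lists. KEGG pathways of the deposited annotation with at least 10 tested genes were also tested with camera, likewise a choice made after seeing the data. One gene was removed from a marker list after the tests, and it and 1 other marker are not reported here. Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9 were used for tables and plots.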

Results

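The series measured polyadenylated transcripts by RNA sequencing in 6 libraries of cells labelled U-937, a line established from a histiocytic lymphoma and widely used as a model of monocytes. Of these, 3 libraries were controls and 3 were labelled FOXO3 knockouts, made with small guide RNAs. FOXO3 (also called FOXO3A) is a forkhead transcription factor that acts downstream of PI3K and AKT signalling and activates genes of cell cycle arrest, apoptosis and oxidative stress defence. The comparison asks how loss of FOXO3 alters gene expression in these cells. Transcripts in all 6 libraries put the label U-937 in doubt, as described further below. CD3E was at 182 FPKM or more in every library, while 26 of 27 monocyte and macrophage markers were below a mean of 1 FPKM. The changes given here are therefore not to be read as changes in monocytic cells. Expression was given as FPKM, and the depth behind it, estimated from the steps between low values, was 5.36, 5.71 and 4.37 gigabases of aligned sequence in the 3 control libraries and 4.26, 4.52 and 4.79 in the 3 knockout libraries. At that depth, and with 282 bases taken as 1 read pair, a transcript of 2 kb at 1 FPKM corresponded to 30.2 to 40.5 read pairs. Nothing in the labels says that the libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

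FOXO3 mRNA was not measurably lower in the libraries labelled knockout. The gene lies on chromosome 6 from 108559835 to 108684774 on the plus strand (GRCh38), and its value in the table covers the whole gene, not the edited site. FOXO3 was at 4.22, 3.63 and 4.27 FPKM in the control libraries (mean 4.04 ± 0.355, SD, n = 3) and at 3.93, 4.13 and 3.46 FPKM in the knockout libraries (3.84 ± 0.346, SD, n = 3). The log2 fold change on the log2(FPKM + 1) scale was −0.06 (SE 0.10, 95% interval −0.29 to 0.17), with a limma adjusted p of 0.732. An exact two-sided permutation test of the FPKM gave p = 0.5, where 0.1 is the smallest value that 3 against 3 libraries allow. Small insertions and deletions can remove a protein and leave its mRNA level in place, so this measurement neither bears out nor refutes the knockout labels, and every direction given here is that of the libraries labelled knockout.

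The paralogs did not differ past the threshold either. FOXO1 was at 1.01 ± 0.151 FPKM in control and 1.13 ± 0.0555 in knockout libraries (limma adjusted p = 0.563). FOXO4 was at 4.88 ± 0.667 and 4.75 ± 0.401 FPKM (adjusted p = 0.893), and FOXO6, named after its value was seen, at 2.01 ± 0.322 and 1.49 ± 0.210 FPKM (adjusted p = 0.205; SD, n = 3 for each group).

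**Figure D1:**
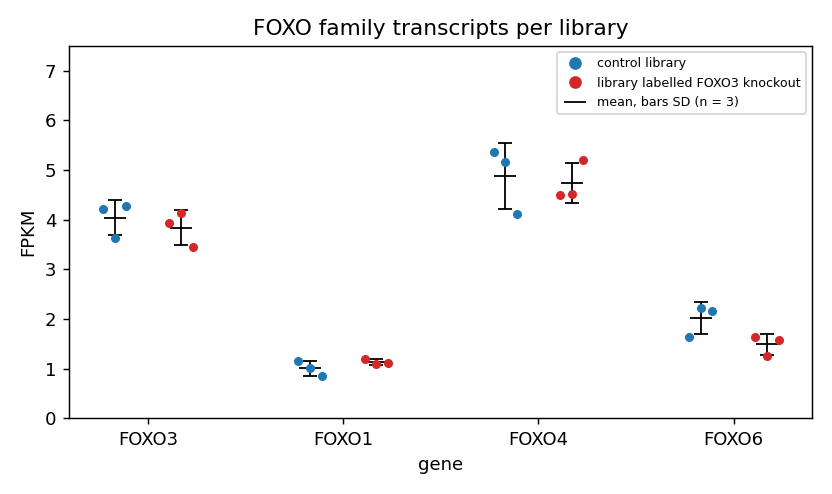
FPKM of the 4 FOXO genes (vertical axis) in each control library (blue) and each library labelled knockout (red), with the mean and SD of each group (n = 3). The FOXO3 values of the groups overlap, with means of 4.04 and 3.84 FPKM.

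Among genes past the threshold, the largest rise on the log2(FPKM + 1) scale was that of CDKN2D. This gene, which encodes the CDK4 and CDK6 inhibitor p19INK4d, rose from 1.39 ± 0.268 to 18.6 ± 0.809 FPKM (SD, n = 3), a log2 fold change of 3.04 (SE 0.10, limma adjusted p = 0.000221). It lies on chromosome 19 from 10566462 to 10569059 (GRCh38). CD40LG, the CD40 ligand of activated T cells, on chromosome X from 136648193 to 136660390, rose from 1.52 ± 0.178 to 15.2 ± 1.60 FPKM (log2 fold change 2.68, SE 0.10, adjusted p = 0.000227). IL26, a cytokine of T cells, rose from 1.67 ± 0.325 to 9.59 ± 0.591 FPKM, and KRT1, a keratin of differentiating epidermis, rose from 6.51 ± 0.199 to 27.5 ± 1.04 FPKM. CGGBP1, which encodes a protein that binds CGG repeats, rose from 3.57 ± 1.28 to 22.0 ± 0.805 FPKM. The others of the 12 largest rises were SLFN5, HPGD (15-hydroxyprostaglandin dehydrogenase), the early activation antigen CD69, HBEGF, KLF2 (a factor of lymphocyte quiescence and migration), CNOT8 (a deadenylase) and the killer cell receptor KIR3DL2, with log2 fold changes between 1.32 and 1.63.

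Among genes past the threshold, the largest fall on the same scale was that of DNTT. This gene, which encodes the terminal transferase that adds nucleotides during V(D)J recombination, on chromosome 10 from 96304396 to 96338564, fell from 58.6 ± 2.21 to 13.4 ± 0.956 FPKM (log2 fold change −2.05, SE 0.07, limma adjusted p = 0.000221). ASS1, argininosuccinate synthase of arginine synthesis, on chromosome 9 from 130444929 to 130501274, fell from 31.6 ± 1.61 to 9.03 ± 0.104 FPKM (log2 fold change −1.70, SE 0.06, adjusted p = 0.000227). IGLL1, a part of the surrogate light chain, fell from 49.0 ± 3.47 to 22.5 ± 2.40 FPKM, and MAL, a membrane proteolipid of T cells, from 8.63 ± 0.503 to 2.67 ± 0.162 FPKM. RHOQ, a small GTPase, fell from 1.85 ± 0.261 to 0.235 ± 0.0178 FPKM. The rest of the 12 were HIST3H2A, HIST1H2BK, EEF1A1P6, GFRA1, SH3GL2, ZNF584 and PTMS. The value of EEF1A1P6 is uncertain because this pseudogene shares sequence with EEF1A1, and those of the histone genes because they share sequence with related histone genes.

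**Figure D2:**
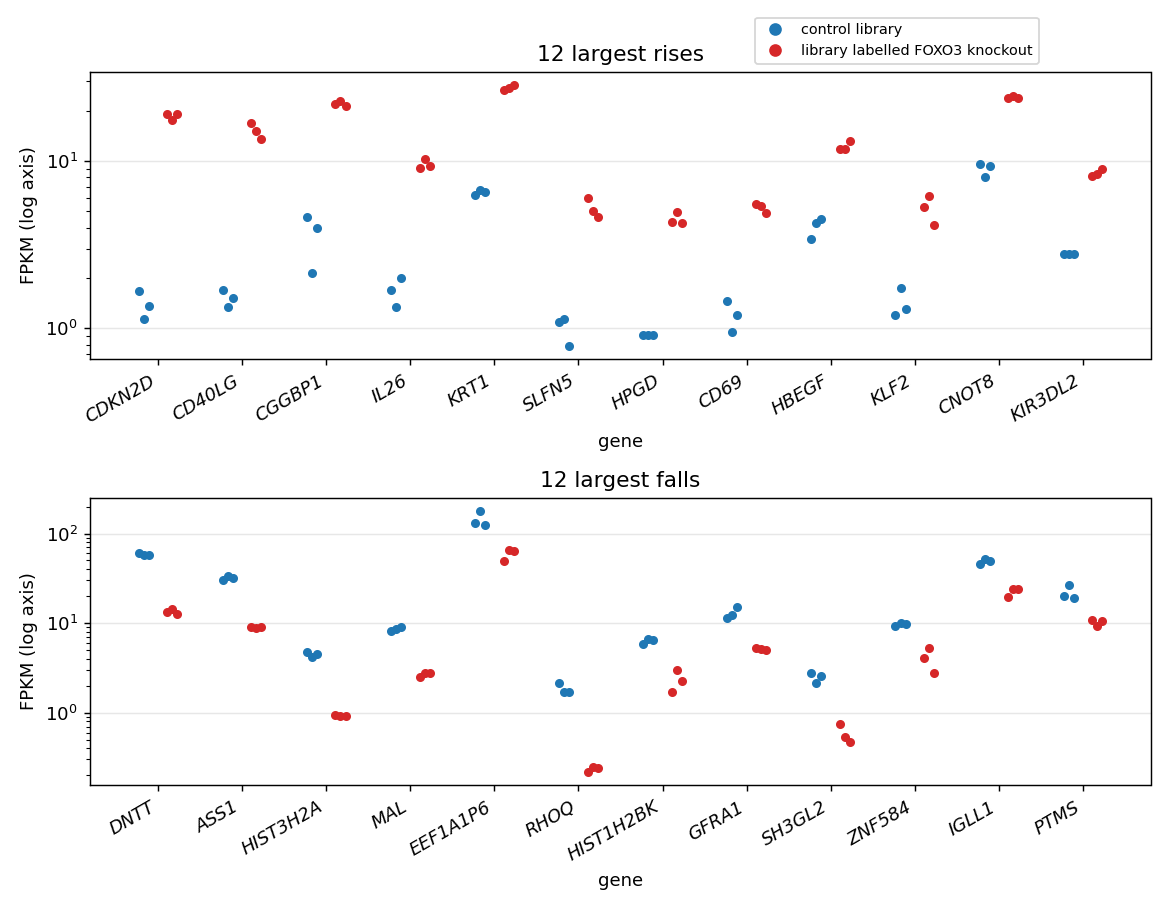
FPKM on a log axis of the 12 genes with the largest rises (top) and the 12 with the largest falls (bottom), with a point for each control library (blue) and each library labelled knockout (red). In each of the 24 genes the 3 knockout values lie on one side of the 3 control values.

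In total 299 of 11162 genes tested changed in the limma model (adjusted p below 0.05), of which 154 rose and 145 fell. At least a 2-fold change on the log2(FPKM + 1) scale was reached by 50 of them (30 rose, 20 fell). Without adjustment 2864 genes were below 0.05, against 558.1 expected by chance, and the groups did not overlap in 32.3% of tested genes, where chance gives 10%. These chance values are averages, and genes that vary together across 6 libraries can move both figures far from them. The log2 fold change also followed GC content across genes, as given below, so the excess is no count of separately regulated genes. Scaling to a common upper quartile gave 170 rises and 259 falls, and removal of a trend with transcript length and GC content gave 315 and 210. The count was 929 without the first control library (674 rises and 255 falls), 122 without the second control, 93 without the third control, 79 without the first knockout library and 68 without the second or the third. With each of the 6 libraries left out in turn, 19 of the 24 largest changes stayed past the threshold. KLF2 missed it without the third control or the first knockout library, HIST1H2BK without the second control, the third control or the third knockout library, and ZNF584 without any of these or the first knockout library. EEF1A1P6 and PTMS missed it without the third control or any knockout library, and the adjusted p of these 5 genes was at most 0.114.

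The second control library stood apart. Its mean correlation with the other group across tested genes was 0.950, against 0.958 to 0.969 for the other libraries. Its mean correlation within its own group was 0.969, close to the 0.971 of the first control. On the first principal component, which held 44.3% of the variance, it lay at −31.3. The other controls lay at −3.71 and −13.6 and the knockout libraries at 10.8 to 19.4. Across genes, which are not independent replicates, the log2 fold change correlated with transcript GC content at a Spearman rho of −0.396, and at −0.313 without the second control. The difference between the second control and the other controls correlated with GC content at a rho of 0.364.

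FOXO target genes did not pass the list test in one direction. Of 23 tested members of that list, 3 rose, 1 fell and 19 did not pass the test, or 3 and 2 when adjusted over the list alone (camera adjusted p = 0.843). The fry test for changes in either direction gave an adjusted p of 0.000166 for this list and was below 0.05 in 22 of the 24 tested lists. The members that rose were KLF2, from 1.42 ± 0.288 to 5.21 ± 1.00 FPKM, CDKN1B, which encodes the cell cycle inhibitor p27, from 31.0 ± 1.37 to 47.9 ± 5.88 FPKM (log2 fold change 0.61, limma adjusted p = 0.0335), and TNFSF10, the death ligand TRAIL, from 0.796 ± 0.0824 to 1.42 ± 0.0241 FPKM (adjusted p = 0.0489). CAT, which encodes catalase, fell from 26.5 ± 0.365 to 20.4 ± 0.625 FPKM (log2 fold change −0.37, adjusted p = 0.0328). BCL2L11, encoding the BH3-only protein BIM, was at 2.33 ± 1.62 and 2.02 ± 1.18 FPKM (adjusted p = 0.951), and GADD45A at 5.24 ± 0.867 and 4.71 ± 0.535 FPKM (adjusted p = 0.584). SOD2 stood only in a row shared with SOD2-OT1, at 3.32 ± 1.65 FPKM in control and 4.05 ± 0.0469 in knockout libraries. TXNIP was below the filter, at 0.0520 ± 0.0361 and 0.0514 ± 0.0583 FPKM. CDKN1B, CAT and TNFSF10 lost the call when any library other than the first control was left out, with adjusted p up to 0.12, 0.132 and 0.177.

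Adhesion and chemotaxis genes were higher as a list (median log2 fold change 0.41, camera adjusted p = 0.0177; adjusted p = 0.722 with an estimated correlation). Of 13 tested members 2 rose, or 7 when adjusted over the list alone, and 11 were higher in the knockout libraries. ITGB7, an integrin subunit of gut-homing lymphocytes, rose from 0.602 ± 0.0683 to 1.49 ± 0.0930 FPKM, and CX3CR1, the fractalkine receptor, from 1.99 ± 0.0854 to 3.17 ± 0.0588 FPKM (limma adjusted p = 0.0205 and 0.0291). ITGAL was at 5.49 ± 0.267 and 10.8 ± 2.79 FPKM (adjusted p = 0.0610) and ITGB2 at 7.41 ± 0.771 and 10.7 ± 0.447 FPKM (adjusted p = 0.0517), the 2 chains of LFA-1. The adjusted p of the list was 0.0246 by fry, 0.148 without the first control library and 0.246 with only genes at a mean of 5 FPKM or more.

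Cytosolic ribosomal protein genes were lower as a list (median log2 fold change −0.27, camera adjusted p = 0.000315; adjusted p = 0.799 with an estimated correlation and 0.169 by fry), with 16 of 17 tested members lower and 0 past the threshold on their own, also when adjusted over the list alone. RPL19 was at 994 ± 72.6 FPKM in control and 820 ± 41.8 in knockout libraries, and RPS4X at 549 ± 50.9 and 432 ± 9.48 FPKM (limma adjusted p = 0.0958 and 0.0680). The adjusted p of the list was 0.105 after quantile normalization. Replication-dependent histones, with 4 tested members, were too few for a list test. HIST1H2AC fell from 2.1 ± 0.176 to 0.744 ± 0.271 FPKM, and the other 3 were lower without passing the test (3 fell when adjusted over the list alone). Among 6 mitochondrially encoded genes, the ribosomal RNA MT-RNR1 rose from 1137 ± 51.5 to 2051 ± 96.3 FPKM (log2 fold change 0.85, limma adjusted p = 0.00389), while the other 5 were lower without passing the test, among them MT-ND2 at 4937 ± 702 and 4225 ± 120 FPKM (camera adjusted p of the list 0.526). MT-ND4 varied widely between libraries, from 39.5 to 128 FPKM in control and from 0.703 to 45.5 FPKM in knockout libraries. Its lower mean is uncertain.

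Cell cycle genes of the G2/M phase included 2 falls and 18 members that did not pass the test, or 9 falls when adjusted over the list alone (camera adjusted p = 0.0589). Of all tested members 11 were lower and 9 higher, with a median log2 fold change of −0.20 and a mean of −0.04. The cyclins that fell were CCNB1, from 77.9 ± 2.62 to 57.2 ± 0.701 FPKM, and CCNB2, from 33.9 ± 0.671 to 24.2 ± 1.47 FPKM (limma adjusted p = 0.0181 and 0.0254). The list passed the threshold without the second or the third control, at an adjusted p of 0.0358 and 0.0366, with no filter on low values (0.00890), after removal of the length and GC trend (0.00219) and after that removal without the second control (0.00119). Its adjusted p was 0.722 with an estimated correlation. None of 24 G1/S genes passed the test (1 rise and 1 fall adjusted over the list alone, camera adjusted p = 0.687), with CCNE2 at 2.44 ± 0.995 and 6.59 ± 1.18 FPKM and CCND2 at 3.88 ± 0.0264 and 2.71 ± 0.206 FPKM.

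Genes of the ATF4 and unfolded protein response moved in both directions. HSPA5, the endoplasmic reticulum chaperone BiP, rose from 94.9 ± 1.42 to 121 ± 1.18 FPKM, and PHGDH, the first enzyme of serine synthesis and a target of ATF4, fell from 21.1 ± 2.04 to 13.1 ± 0.676 FPKM (limma adjusted p = 0.0254 and 0.0225). The other 20 of 22 members did not pass the test, and 4 rose and 9 fell when adjusted over the list alone (camera adjusted p = 0.0582). In the knockout libraries 16 members were lower and 6 higher (median log2 fold change −0.23). The list passed the threshold, as lower, without the first control, the third control or the third knockout library (camera adjusted p = 0.0485, 0.0359 and 0.0379). Its adjusted p was 0.799 with an estimated correlation. Oxidative phosphorylation genes included 0 changed members of 19, with 15 lower (camera adjusted p = 0.0582), and this list passed the threshold without the first control or the third knockout library, at an adjusted p of 0.0126 and 0.0215, with no filter on low values (0.00890) and with upper-quartile scaling (0.0488). Its adjusted p was 0.799 with an estimated correlation.

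Single members passed the test in 4 further lists. RUNX1, a transcription factor of haematopoietic progenitors, rose from 15.7 ± 0.907 to 21.1 ± 0.687 FPKM as the 1 change among 9 leukaemia stem cell and progenitor genes (3 rose adjusted over the list alone, camera adjusted p = 0.175). NT5C3A, a pyrimidine nucleotidase, rose from 6.95 ± 0.735 to 11.1 ± 0.456 FPKM among 12 drug transport and nucleoside metabolism genes (2 over the list alone, camera adjusted p = 0.687). Catalase was the 1 change among 19 antioxidant genes (1 rise and 1 fall over the list alone, camera adjusted p = 0.281). CD2, an adhesion receptor of T and natural killer cells, rose from 1.39 ± 0.287 to 3.16 ± 0.102 FPKM among 9 lymphoid markers (3 rises and 1 fall over the list alone, camera adjusted p = 0.201). Of the 15 named list members and FOXO targets past the threshold besides the largest changes, MT-RNR1 kept its call with each library left out, and the other 14 lost it in 4 or 5 of the 6 leave-outs, none of them without the first control, with highest adjusted p between 0.0867 and 0.177.

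No member passed the test in the remaining 12 lists that were tested. Cholesterol synthesis genes had 4 rises over the list alone (camera adjusted p = 0.201), with HMGCS1 at 39.7 ± 15.6 and 86.3 ± 7.51 FPKM. Antigen presentation genes had 3 (camera adjusted p = 0.175, and 0.0243 after removal of the length and GC trend without the second control; adjusted p = 0.799 with an estimated correlation), with B2M at 75.9 ± 4.12 and 90.1 ± 0.596 FPKM, and heat shock genes had 3 (camera adjusted p = 0.642), with HSP90AA1 at 350 ± 44.9 and 474 ± 35.4 FPKM. Glycolysis and hypoxia genes had 3 rises and 1 fall over the list alone (camera adjusted p = 0.723). Genes of p53 had 1 rise and 2 falls (camera adjusted p = 0.687), with CDKN1A at 0.850 ± 0.217 and 2.17 ± 0.707 FPKM. Interferon-stimulated genes had 1 fall (camera adjusted p = 0.687), and immediate-early genes had 1 fall (camera adjusted p = 0.363). Apoptosis genes (camera adjusted p = 0.833), autophagy and lysosome genes (0.682), inflammatory NF-kB genes (0.833), DNA repair genes (0.790) and MYC and ribosome biogenesis genes (0.281) had 0 over the list alone.

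**Figure D3:**
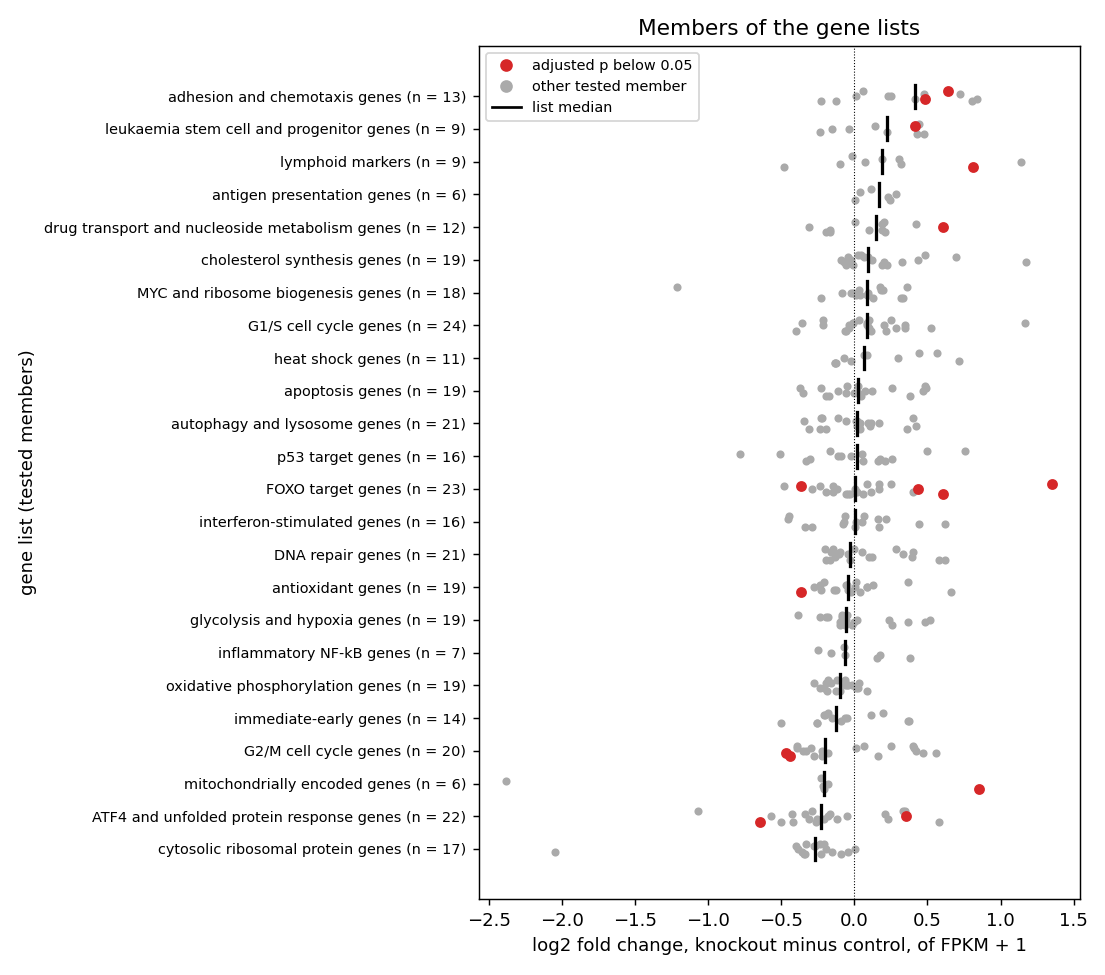
Log2 fold change of FPKM + 1 (horizontal axis, knockout minus control) of each tested member of the 24 tested gene lists, with members past the threshold in red, others in grey and the list median as a black bar. The medians run from −0.27 for cytosolic ribosomal proteins to 0.41 for adhesion and chemotaxis genes.

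Markers of monocytes were low and markers of T cells abundant in all 6 libraries. Of 27 monocyte and macrophage markers with a row in the table, 26 were below a mean of 1 FPKM, and CEBPB was the 1 tested member, at 4.21 ± 0.585 FPKM in control and 3.60 ± 0.358 in knockout libraries (limma adjusted p = 0.361). Among 20 neutrophil granule genes 3 were tested, and CTSG, encoding cathepsin G, fell from 65.3 ± 9.75 to 38.4 ± 0.825 FPKM (adjusted p = 0.0275), while CST7 and SRGN did not pass the test. Erythroid and megakaryocyte markers had 1 tested member (EPOR, 1.91 ± 0.222 and 1.52 ± 0.278 FPKM) and epithelial and fibroblast markers had 1 (KRT18, 1.23 ± 0.218 and 1.02 ± 0.484 FPKM). Among the lymphoid markers CD3E, a signalling chain of the T cell receptor complex, was at 201 ± 16.8 and 211 ± 13.6 FPKM (limma adjusted p = 0.626). CD3D was at 170 ± 12.8 and 212 ± 6.99 FPKM (limma adjusted p = 0.0671). CD79A, a signalling chain of the B cell receptor complex, was at 39.4 ± 3.84 and 28.1 ± 3.69 FPKM (limma adjusted p = 0.0741).

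**Figure D4:**
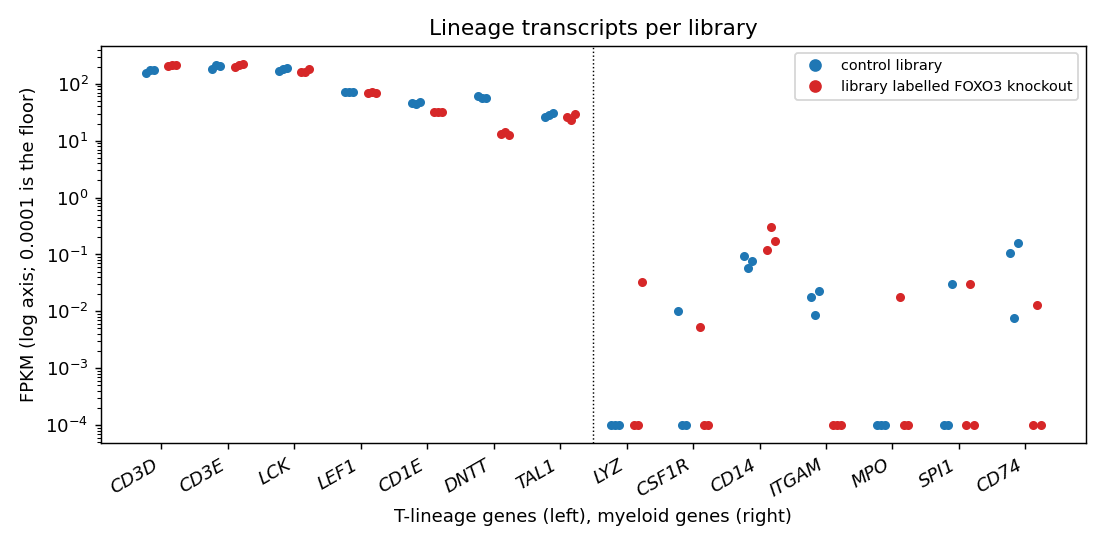
FPKM on a log axis of 7 T-lineage genes (left) and 7 myeloid genes (right), chosen after their values were seen, with a point for each control library (blue) and each library labelled knockout (red); 0.0001 is the floor of the table. CD3E was at 182 FPKM or more in all 6 libraries, while each myeloid gene shown stayed below 1 FPKM in all of them.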

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

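The removal of a trend with length and GC content, that removal without the second control library, and the lists with rows naming several genes were chosen after seeing the data. The count of 299 changed genes was 193 with no filter on low values, 542 after quantile normalization, 525 after removal of the length and GC trend, and 68 to 929 with each library left out. The cause of these shifts was not tested. All 299 genes kept their sign in each alternative that tested them (198 were tested at a mean of at least 5 FPKM). In all 299 the groups did not overlap, so most alternatives could not have turned a sign. This holds for each library left out and for the pseudocount, the filter, the variance trend and the replicate block. The log2 fold change of FOXO3 ran from −0.12 to 0.00 with each library left out, was 0.000274 without the third knockout library (adjusted p 0.999; 0.488 to 0.999 over the leave-outs), and passed no threshold in any alternative; at a mean of at least 5 FPKM it was not tested. The 2 lists past the threshold became 5 with no filter, 1 at a mean of at least 5 FPKM, 1 after quantile normalization, 1 with fry, 0 with an estimated correlation, 4 after length and GC removal without the second control, and 2 to 4 with each library left out. With a replicate block 27 genes changed and 2 lists passed. Same-numbered libraries deviated with correlations of 0.0984, −0.0392 and 0.0162. Of the controls, only the first correlated best with the knockout library of its number. These values gave no clear sign of pairs, but so few correlations cannot exclude a shared batch, so the replicate block stays a possible model. Among 132 named genes, 39 of them past the threshold, no call turned in direction, which most alternatives could not have done for those 39. Over 2053 pairs of a gene and a setting 130 lost the call and 71 gained it, with 24 lost under the replicate block and 11 with no filter. The count test was not run, since whole reads were not recovered. Depth differed by a factor below 1.5 between libraries.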

Other observations

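The tests of lineage, of the FOXO3 transcript, of chance and of distribution and length effects were chosen after results had been seen, and the test of genes matched on abundance was not. Several lymphocyte genes outside the naming rule, chosen after their values were seen, rose in the libraries labelled knockout. GZMA, encoding granzyme A, rose from 29.6 ± 1.32 to 70.0 ± 2.71 FPKM (log2 fold change 1.22, limma adjusted p = 0.000818), and EOMES, a T-box factor of effector lymphocytes, from 1.10 ± 0.172 to 3.01 ± 0.261 FPKM (adjusted p = 0.0111). TRAT1 rose from 5.99 ± 0.708 to 12.6 ± 1.11 FPKM, THEMIS from 2.0 ± 0.478 to 4.71 ± 0.639 FPKM and BCL11B from 12.8 ± 0.372 to 16.7 ± 0.575 FPKM (adjusted p = 0.0116, 0.0301 and 0.0450). GZMK was listed at the floor in the 3 control libraries and at 1.25, 1.06 and 1.05 FPKM in the knockout libraries, the 1 gene with such a pattern at 1 FPKM or more, and another split of the libraries also gave 1. The related GZMB, below the filter, was lower without overlap of the groups, at 0.931 ± 0.155 FPKM in control and 0.415 ± 0.142 in knockout libraries.

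Of 11 genes of immature thymocytes 4 fell and 0 rose, namely DNTT, IGLL1, CD1D (19.4 ± 0.369 to 12.9 ± 0.420 FPKM, limma adjusted p = 0.0118) and CD1E (46.2 ± 2.53 to 32.2 ± 0.528 FPKM, adjusted p = 0.0176). Of 19 T-lineage core genes 4 rose and 0 fell. These lists were written after some of the values were seen, so their counts describe the data and test nothing. Among 286 KEGG pathways of the deposited annotation, 1 passed the threshold, Ribosome, lower in the knockout libraries (126 genes, 1 rose, 4 fell, median log2 fold change −0.17, camera adjusted p = 5.25e-06), at an adjusted p of 0.999 with an estimated correlation. After removal of the length and GC trend 3 passed, namely Ribosome (lower, adjusted p = 0.000238), Viral myocarditis (higher) and Valine, leucine and isoleucine degradation (lower, adjusted p = 0.00389 for both); before that removal the adjusted p of each was 0.999 with an estimated correlation. The T cell receptor signalling pathway had 4 rises and 0 falls among 75 genes (camera adjusted p = 0.226).

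All 6 libraries carried T-lineage transcripts, while 26 of 27 monocyte and macrophage markers and 17 of 20 neutrophil granule genes were below a mean of 1 FPKM (the exceptions CEBPB, CTSG, CST7 and SRGN were at 3.24, 37.6, 12.9 and 9.28 FPKM or more in every library). A mixture of U-937 cells with T cells is argued against by the fixed monocyte and macrophage list, whose median was 0.0275 FPKM. LYZ, MPO, CSF1R and SPI1 were below 1 FPKM in every library. Single mislabelled libraries, or an effect of the knockout, as the source of the T-lineage transcripts are argued against by CD3E. It was at 182 FPKM in the lowest library, controls included. CD3E cannot show a swap between control and knockout libraries, since it was alike in both groups (201 ± 16.8 and 211 ± 13.6 FPKM). Polyclonal T cells are argued against by the TRBV signal, of which 2 rows, TRBV12-3 and one shared by TRBV12-3 and TRBV12-4, held at least 91.9% in every library; the row of TRBV12-3 alone held 43.8% in the lowest library, under the 50% set for 1 gene. A line of T lineage in all 6 cultures remains a candidate explanation: of the fixed lymphoid markers, CD3D, CD3E, CD3G, CD2, CD7 and LCK had a median of 106 FPKM, while MS4A1, PAX5, CD79B, GNLY, KLRD1 and GZMB were below a mean of 1 FPKM, and CD79A, NKG7 and PRF1 were at 25.2, 2.37 and 2.14 FPKM or more in every library. TAL1 with TRBV12-3 and TRAV8-4 may point to a T-cell leukaemia line such as Jurkat, a hypothesis that expression alone cannot settle.

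Ribosomal protein transcripts were lower in the libraries labelled knockout, with a list median of −0.27 (quartiles −0.35 and −0.19). The camera call was lost with an estimated correlation (adjusted p = 0.799) and by fry (adjusted p = 0.169). Length and GC bias as the whole cause is argued against by the list after removal of that trend. The list median was then −0.18 (quartiles −0.29 and −0.07), with a camera adjusted p of 0.00317 at the preset correlation. An estimated correlation and fry were not run after that removal, so this p-value rests on the preset correlation. A fall of all abundant transcripts is argued against by 99 other genes matched on abundance and length, whose median was −0.01 (−0.00738, quartiles −0.20 and 0.09). Without the second control the median was −0.19. A difference in the shape of the value distributions stays open: quantile normalization moved the median to −0.11 (−0.113; quartiles −0.21 and −0.09), and the call ended (adjusted p = 0.105) as the mean z of the members moved from −1.70 to −1.16 and that of the other genes from 0.150 to −0.0733. An effect of FOXO3 loss also remains open, as untested.

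The FOXO3 transcript was not measurably lower in the libraries labelled knockout (means of 4.04 FPKM in control and 3.84 in knockout libraries). Loss of the transcript in all cells, by deletion or decay, is argued against by the 95% interval of the fold on the log2(FPKM + 1) scale, whose lower bound was 0.819. Whether editing left FOXO3 function in place cannot be told apart from a frameshift that spares the mRNA. The FOXO target list had a camera adjusted p of 0.843. Of its members past the threshold, 3 were higher in the knockout libraries (KLF2, CDKN1B and TNFSF10) and 1 was lower (CAT). The fry adjusted p of this list for changes in either direction was 0.000166, which speaks against unchanged targets, but 22 of the 24 tested lists were below 0.05 in this test, so it is not specific to FOXO3, and the edited site was not analysed here. Of the 10 splits of the 6 libraries, 1, the real one, gave 299 changed genes, and the highest of the others gave 6, but 10 splits are too few for a share under 0.05. Each of the other splits also mixes control and knockout libraries. Any difference between the groups then adds to the spread within a split and lowers its count, so these low counts say little about chance.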
